A study of Mus musculus with 8 samples.

How the data were processed

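The data are 8 Illumina mouse BeadArrays with 25697 probes, each hybridised with Cy5-labelled total RNA from frozen liver outside tumours of male A/J mice. The arrays form 4 groups of 2 per the labels: vehicle, CCl4, CCl4 with erlotinib 2 mg and CCl4 with erlotinib 5 mg. Replicate numbers follow the order of the records and carry no pairing. Neither slides nor dates of labelling nor the time of day of death are given in the sources used here, so a difference between such batches cannot be told apart from a difference between groups. The labels do not say that the arrays of a group are separate animals, so each p-value describes the spread between these arrays. Sample titles give the vehicle arrays codes that start with OO and all other arrays codes that start with CT. What the codes mean is not stated, and any difference they mark coincides with CCl4 against vehicle.

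The deposited table of non-normalized values holds the intensity of each probe on each array, a bead summary on a linear scale without background subtraction or scaling between arrays. A separate deposited table holds intensity values normalized between arrays by the authors by a method that is not stated, and it served as an alternative. The rank correlation of the 2 tables was 0.9996 to 0.9999 for the same array and at most 0.766 for different arrays. Array medians were 99.8 to 130 in the first and near 117 in the second. No detection p-value is in the files, so the procedure set for that case was followed: limma (version 3.58.1, in R 4.3.3) normexp background correction with an offset of 50, quantile normalization and log2.

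Of the probes, 23978 carried 1 current gene symbol, 0 several and 1719 none. Probes with a mean log2 intensity above the 40th percentile were kept (15418), and the probe with the highest mean stood for each gene, which left 11022 genes. Background on an array was taken as the 99th percentile of the intensity of 1324 probes for odorant, vomeronasal and trace amine receptors, 111 to 145 before correction, a limit chosen in place of the detection p-value. By it 4405 of the tested genes were under background on every array. A change is given as "at least N-fold" where every array of one group was under background, computed against that limit, and where only part of a group was under background the log2 change is given, with a less certain size. Of 546 tested receptor genes 5 passed the threshold with CCl4 and 2 with erlotinib. Probes without a symbol (980 kept) were tested separately.

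All groups were fitted in 1 limma model (lmFit and eBayes, 4 residual and 11.9 prior degrees of freedom) with contrasts for CCl4 against vehicle, each erlotinib dose against CCl4, both doses against CCl4 and 5 mg against 2 mg. A gene is called changed at a Benjamini-Hochberg adjusted p under 0.05. The 41 gene lists, written before the data were examined, were tested with limma camera against all other genes with the preset correlation of 0.01, then with an estimated correlation and with fry, and p-values were adjusted over the 40 lists with at least 5 measured genes; erythroid markers had 4 and were not tested. Counts adjusted over the list alone use the genes of that list as the only tests.

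Genes were named by a rule set in advance. It took the 10 largest rises and falls among called genes whose groups do not overlap, the 5 smallest p-values per direction where fewer than 10 genes passed, up to 4 called members of each list that shifted, and a fixed set with Egfr, its ligands, collagens, Acta2, Timp1, Tgfb1, Cyp2e1 and others. Of the fixed genes, Egf, Tgfa, Col1a2, Pdgfrb and Afp had 1 probe each above background on 0 arrays, and Areg and Mki67 had no listed probe. Members that opposed their list, other genes of lists that missed the threshold and the additional members named were chosen after their values were seen.

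For changes that share the CCl4 arrays, unchanged groups were simulated 100 times with the same sharing, and the CCl4 arrays were also split, 1 to each comparison. The groups, tests, lists and most alternatives were fixed before the data were examined. The alternatives were the authors' values, no background correction, median scaling, no filter on dim probes, an intensity trend with a robust prior, the mean of the probes of a gene, only the compared arrays, array weights and each array left out in turn. Filters on probes above the receptor background on at least 2 arrays or on all 8 arrays, and the comparison of erlotinib with vehicle, were added after the data were seen. A filter on detection p-values and a slide effect were not run, since neither is in the files. With 1 array of a group left out, the lone array is assumed to vary like the other groups.

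The fit and its calls were tested on simulated data with 200 changed genes, drawn as independent normal noise on the normalized scale. Background correction, normalization, the probe filter and the choice of probe were not part of this test, so its rates do not cover them. Of genes changed 1.5-fold, 83.4% to 84.8% were recovered in the comparisons of 2 arrays with 2 and 95.5% in that of 4 with 2, and at 2-fold at least 99.9% in each. False calls were 5.95% to 7.31% of all calls, above the intended level. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.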

Results

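Gene expression was measured on 8 Illumina mouse BeadArrays, each hybridised with RNA from the liver of male A/J mice. A/J is an inbred laboratory strain. There were 4 groups of 2 arrays each: oil vehicle, carbon tetrachloride (CCl4), CCl4 with erlotinib at 2 mg and CCl4 with erlotinib at 5 mg. CCl4 is a hepatotoxin that hepatocytes turn into a reactive radical, chiefly through Cyp2e1, and repeated dosing scars the liver. Erlotinib inhibits the kinase of the epidermal growth factor (EGF) receptor. CCl4, as a 40% solution, or vehicle was given by gavage 3 times per week for 18 weeks. The protocol places the taking of livers in week 19 after a washout of 1 week, while the source of each sample reads week 18, and which holds is not given in the sources used here. The RNA came from liver outside any tumour. The unit of weight behind the erlotinib doses and the dosing schedule are not given in the sources used here.

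Median raw intensity per array lay between 99.8 and 130, and 23.0% to 26.1% of probes stood above the background of each array. After normalization, arrays of one group correlated at 0.984 to 0.988 across genes (genes are not independent replicates), and the SD of their difference was 0.185 to 0.213 on the log2 scale. The first principal component held 50.4% of the variance and placed the CCl4 arrays at -20.3 and -27.2, the vehicle arrays at 16.7 and 15.4 and the erlotinib arrays between 0.728 and 5.23. The second held 18.7% and placed the erlotinib arrays at -6.64 to -11.9, below the CCl4 arrays at 2.40 and 7.87 and the vehicle arrays at 12.6 and 10.8. Values given as log2 ± SE are differences between group means of 2 arrays, and adjusted p-values are those of limma with Benjamini-Hochberg adjustment over 11022 genes. The number of arrays limits the precision, and since nothing states that the arrays of a group come from separate animals, p-values measure the spread between arrays.

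The comparison of CCl4 with vehicle asked what chronic CCl4 did to the liver. Among the genes that rose were those of secreted and membrane proteins of epithelium, stellate cell actin and a G1 cyclin, and among those that fell were cytochrome P450 enzymes. Lcn2, an iron-sequestering protein secreted by injured epithelium, rose by 5.14 ± 0.25 (adjusted p 9.89e-10), and the membrane protein gene Ly6d was at least 21.9-fold higher (adjusted p 2.27e-11). Acta2, the smooth muscle actin of activated stellate cells, rose by 2.26 ± 0.27 (adjusted p 2.00e-05) and Ccnd1, the cyclin of G1 entry, by 2.85 ± 0.22. Cyp2e1 fell by 1.97 ± 0.22 (adjusted p 9.51e-06), and Cyp7b1, an oxysterol hydroxylase, changed by -3.54 ± 0.17 (adjusted p 9.89e-10).

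In all, 1398 genes changed, 744 higher and 654 lower, and 303 of them changed at least 2-fold. In all 1398 the 2 arrays of one group lay on one side of the 2 arrays of the other, as did 48.6% of all genes tested, where chance alone gives 33.3%. Other large rises were those of Anxa2 (4.04 ± 0.25), Serpina7, which encodes thyroxine-binding globulin (3.92 ± 0.25), the lysosomal membrane gene Cd63 (3.35 ± 0.12), S100a11 (3.35 ± 0.20), the keratin gene Krt8 (3.32 ± 0.23), the endotoxin co-receptor Cd14 (3.17 ± 0.20) and Fkbp11 (3.08 ± 0.13), and Wfdc3 was at least 8.25-fold higher. Other Cd63 probes gave smaller rises (1.25 and 1.98). Large falls were in major urinary protein genes (Mup21 -4.25 ± 0.29, Mup2 -3.59 ± 0.35, Mup6 -3.34 ± 0.30, Mup20 -3.26 ± 0.28) and the steroid dehydrogenase Hsd3b5, at least 12.8-fold lower. Serpina1e (-3.35 ± 0.37), Car3 (-3.30 ± 0.35), Cyp8b1, the 12-alpha-hydroxylase of bile acid synthesis (-3.25 ± 0.42), and Ces3b (-3.07 ± 0.23) fell too. The CCl4 arrays differed widely for Car3 (SD 1.30), and the call on Cyp8b1 ended with an intensity trend in the prior (adjusted p 0.0827).

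Some matrix genes rose with CCl4. Of 15 measured basement membrane and matrix glycoprotein genes, 5 rose and 1 fell (6 and 1 when adjusted over the list alone), with a list adjusted p of 9.12e-05 by camera, and adjusted p = 0.0722 with an estimated correlation. They included the type IV collagen Col4a1 (1.42 ± 0.12) and Sparc (1.17 ± 0.12), while Col18a1 changed by -0.79. A second Sparc probe, above background on all 8 arrays, gave a smaller rise (0.55, adjusted p 0.0215). Of 16 matrix crosslinking and turnover genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone; list adjusted p 0.000259, and adjusted p = 0.0946 with an estimated correlation). The metalloproteinase inhibitor Timp1 was at least 2.33-fold higher, the lysyl oxidase Loxl1 at least 1.43-fold and the gelatinase Mmp2 at least 1.46-fold. Among 7 fibrillar collagen genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), but the list missed its threshold (adjusted p 0.0513). Col1a1 was at least 1.34-fold higher (adjusted p 0.00195), and the value of Col3a1 was -0.01 (adjusted p 0.984). The Col3a1 probe stood at 6.01 on the log2 scale with vehicle, under the array median of 6.15, so it cannot show whether Col3a1 changed.

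Of 22 stellate cell and myofibroblast markers 6 rose and 0 fell (7 and 0 adjusted over the list alone; list adjusted p 0.00398, and adjusted p = 0.0946 with an estimated correlation). Besides Acta2 these included the small proteoglycan Lum (0.82) and, at least 1.56-fold higher each, Vim and Cygb. Of 16 genes of the TGF-beta family and its targets 4 rose and 0 fell (4 and 0 adjusted over the list alone; list adjusted p 0.00398, and adjusted p = 0.0946 with an estimated correlation): Ccn2 (1.27), Tgfbr2 (0.82), Tgfbi (0.58) and Tgfb1 (0.39, adjusted p 0.0356). A second Tgfbi probe missed (0.33, adjusted p 0.114). The call on Acta2 ended when the prior was fitted with an intensity trend (adjusted p 0.0537), and of 2 other Acta2 probes 1 passed (0.58, adjusted p 0.00516) and 1, above background on 2 arrays, missed. That on Tgfb1 ended without CCl4 replicate 1 or 2 (adjusted p 0.174 and 0.0874) or vehicle replicate 1 or 2 (0.0980 and 0.209), and that on Tgfbi without CCl4 replicate 2 (0.0534) or vehicle replicate 2 (0.0963).

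Some epithelial and macrophage markers rose as well. Of 14 cholangiocyte and ductular markers 3 rose and 0 fell (4 and 0 adjusted over the list alone; list adjusted p 0.00398, and adjusted p = 0.212 with an estimated correlation), and these were the keratins Krt8, Krt18 (2.66) and Krt23 (1.04), of which hepatocytes also express the first pair. Of 14 oncofetal and tumour-associated genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; list adjusted p 0.000308, and adjusted p = 0.134 with an estimated correlation): Lcn2, Ly6d, Ccn2 and Golm1, the last at least 1.47-fold. The oncofetal marker Gpc3 had a value of 0.12 (adjusted p 0.727), and the single probe of Afp was under background on every array. The Gpc3 probe was dim, at 6.22 on the log2 scale with vehicle beside an array median of 6.15. The call on Krt23 ended without CCl4 replicate 2 (adjusted p 0.0524) or vehicle replicate 1 (0.117). Of 22 Kupffer cell and macrophage markers 10 rose and 1 fell (14 and 1 adjusted over the list alone; list adjusted p 1.75e-10, and adjusted p = 0.0722 with an estimated correlation). Cd14, the lysozyme genes Lyz1 (1.91) and Lyz2 (1.80) and Gpnmb, at least 3.78-fold higher on 1 of 4 probes, the others at or near background, led them, and the mannose receptor Mrc1, which sinusoidal endothelium also expresses, changed by -0.56.

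Of 33 interferon response genes 15 rose and 0 fell (22 and 0 adjusted over the list alone; list adjusted p 3.48e-11, and adjusted p = 0.0967 with an estimated correlation), led by Usp18 (2.42), Ifi27 (1.72), Isg15 (1.48) and the GTPase Igtp (1.37). Of 13 antigen presentation genes 5 rose and 0 fell (7 and 0 adjusted over the list alone; list adjusted p 0.00344, and adjusted p = 0.0967 with an estimated correlation), with Cd74, the class II invariant chain, at 1.47 ± 0.32. Of 10 neutrophil markers only Lcn2, which epithelium also makes, and S100a8, at least 1.26-fold higher, rose and 0 fell (2 and 0 adjusted over the list alone; list adjusted p 0.0253, and adjusted p = 0.226 with an estimated correlation). Markers of T and NK cells (0 of 16 changed, 0 adjusted over the list alone; list adjusted p 0.842) and of B cells (1 of 8 rose, 1 adjusted over the list alone; list adjusted p 0.968) did not pass, nor did 28 endothelial markers, of which 1 rose and 3 fell (1 and 3 adjusted over the list alone; list adjusted p 0.248). The call on Cd74 ended with the authors' processed values, with median scaling and without vehicle replicate 1 (adjusted p 0.0710, 0.0666 and 0.0828). The call on neutrophil markers ended with both of these scalings and without CCl4 replicate 1 (adjusted p 0.0750) or vehicle replicate 2 (0.105).

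Genes of several hepatocyte functions fell. Of 32 complement and coagulation genes 15 fell and 0 rose (22 and 0 adjusted over the list alone; median -0.41, list adjusted p 1.07e-14, and adjusted p = 0.0722 with an estimated correlation), led by plasma kallikrein Klkb1 (-1.84) and F13b (-1.41). Of 28 urea cycle and amino acid breakdown genes 15 fell and 0 rose (16 and 0 adjusted over the list alone; list adjusted p 2.27e-11, and adjusted p = 0.0754 with an estimated correlation), among them Haao (-1.55), the proline dehydrogenase Prodh (-1.45) and Hpd (-1.44). Genes of both liver zones were among those that fell. Of 23 periportal genes 15 fell and 0 rose (17 and 0 adjusted over the list alone; list adjusted p 1.20e-10, and adjusted p = 0.0690 with an estimated correlation), such as Ftcd (-1.21) and argininosuccinate lyase Asl (-1.19). Of 25 pericentral genes 10 fell and 2 rose (11 and 2 adjusted over the list alone; list adjusted p 8.99e-07, and adjusted p = 0.0946 with an estimated correlation), with Cyp2c50 at -2.82, Cyp2c37 at -2.67 and Cyp1a2 at -2.29 ± 0.16. Albumin (Alb) changed by -0.70 ± 0.16 (adjusted p 0.00557), a call that ended with median scaling (0.310) or without CCl4 replicate 1 or vehicle replicate 1. Its probe stood at only 7.54 on the log2 scale with vehicle, beside 13.9 for the fibrinogen gene Fga. The value may therefore not measure albumin transcripts.

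Drug metabolism split. Of 49 cytochrome P450 and phase II genes 16 fell and 6 rose (18 and 6 adjusted over the list alone; list adjusted p 9.12e-05, and adjusted p = 0.0967 with an estimated correlation). The risers were the fatty acid hydroxylase Cyp4a14 (1.51), the epoxide hydrolase Ephx1 (0.91) and the glutathione transferases Gsta1 (at least 3.12-fold), Gstm1 (0.75), Gstm2 (0.76) and Gstp1 (0.89). Of 25 antioxidant NRF2 targets 8 rose and 2 fell (8 and 2 adjusted over the list alone; list adjusted p 0.00612, and adjusted p = 0.113 with an estimated correlation), with sulfiredoxin Srxn1 at 2.29. A second Srxn1 probe gave a smaller rise (0.90). Abcc3 (-0.96) and Gclm (-0.64), a subunit of the glutathione synthesis enzyme, went the other way. Of 26 metallothionein and acute phase genes 10 rose and 3 fell (10 and 3 adjusted over the list alone; list adjusted p 0.00252, and adjusted p = 0.274 with an estimated correlation): Orm2 was at 2.15 and Lrg1 at 1.30, but Saa4 was at -1.31. The hepcidin genes parted, with Hamp2 at -2.74 and Hamp at 1.29 (adjusted p 0.0309), a call that ended without CCl4 replicate 2 (0.263), vehicle replicate 1 (0.415) or either erlotinib 2 mg array (0.0526). Median scaling ended the call on the metallothioneins and acute phase genes (adjusted p 0.0626).

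Some lipid and bile acid genes fell. Of 24 bile acid genes 11 fell and 0 rose (11 and 0 adjusted over the list alone; list adjusted p 8.02e-08, and adjusted p = 0.0946 with an estimated correlation), and beside Cyp8b1 and Cyp7b1 these included the sterol exporter Abcg8 (-1.25) and Slc27a5 (-1.07). Of 17 cholesterol synthesis genes 7 fell and 0 rose (8 and 0 adjusted over the list alone; list adjusted p 8.99e-07, and adjusted p = 0.107 with an estimated correlation), with Hsd17b7 at -1.15 and Mvd at -0.66. Of 22 fatty acid and triglyceride synthesis genes 6 fell and 1 rose (10 and 1 adjusted over the list alone; list adjusted p 0.000301, and adjusted p = 0.0722 with an estimated correlation). The lipogenic regulators Thrsp (-2.92 ± 0.28) and Mlxipl (-1.30) fell and the lipid droplet coat gene Plin2 rose (0.89). Of 29 fatty acid oxidation genes 10 fell and 1 rose (12 and 1 adjusted over the list alone; list adjusted p 0.00193, and adjusted p = 0.169 with an estimated correlation), Acaa1b being at -1.10.

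Of 23 male-biased and growth hormone dependent genes 12 fell and 0 rose (13 and 0 adjusted over the list alone; median -0.63, list adjusted p 2.70e-10, and adjusted p = 0.0711 with an estimated correlation), Hsd3b5, Mup2, Cyp7b1 and Serpina1e leading. Of 16 circadian clock genes 4 fell and 0 rose (7 and 0 adjusted over the list alone; list adjusted p 0.00142, and adjusted p = 0.227 with an estimated correlation). The nuclear receptor Nr1d1 was at -1.12 ± 0.12 (adjusted p 6.29e-06), with 1 of its 2 CCl4 arrays under background, and a second Nr1d1 probe, above background on 5 arrays, missed (-0.34, adjusted p 0.282). The clock output gene Dbp was at least 3.5-fold lower (adjusted p 0.0167). The call on Dbp ended without CCl4 replicate 1 or 2 (adjusted p 0.0549 and 0.0997), without vehicle replicate 1 (0.196) and with median scaling (0.340). Probes of the Mup, Cyp2c, Cyp2b, Cyp4a, Ugt, Gst and Acot families and of Lyz1 and Lyz2 may bind transcripts of close relatives, so their gene names are uncertain.

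Ribosomal protein genes rose, as did some proteasome and stress response genes, and some respiratory chain genes fell. Of 44 cytosolic ribosomal protein genes 33 rose and 0 fell (37 and 1 adjusted over the list alone), with a median of 0.75, a list adjusted p of 1.51e-25, and adjusted p = 0.0711 with an estimated correlation, as in Rpl12 (1.30) and Rpl35 (1.22). Of 24 proteasome genes 8 rose and 0 fell (11 and 0 adjusted over the list alone; list adjusted p 0.000301, and adjusted p = 0.105 with an estimated correlation), with Psmd13 at 0.83. Of 26 unfolded protein and integrated stress response genes 8 rose and 1 fell (9 and 1 adjusted over the list alone; list adjusted p 9.12e-05, and adjusted p = 0.0946 with an estimated correlation). Ddit3, the stress-induced transcription factor CHOP, rose by 2.52 ± 0.16, and Herpud1, also a stress target, changed by -0.80. The heat shock list did not pass (3 rose and 0 fell of 14, 3 and 0 adjusted over the list alone; list adjusted p 0.129). Of 52 oxidative phosphorylation genes 11 fell and 0 rose (12 and 0 adjusted over the list alone; median -0.18, list adjusted p 9.02e-05, and adjusted p = 0.0711 with an estimated correlation), with Cox6c at -0.70.

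Growth factor genes were mixed. The EGF receptor gene Egfr changed by -1.34 ± 0.24 (adjusted p 0.000895), and the ligand gene Hbegf had a value of -0.17 (adjusted p 0.511). The Hbegf probe was dim, at 6.37 on the log2 scale with vehicle beside an array median of 6.15. The ligand gene Nrg1, which is named here after its value was seen, was at least 1.61-fold higher. The list of 8 EGF receptor family genes did not pass (1 rose and 1 fell, 1 and 1 adjusted over the list alone; list adjusted p 0.554), and the Egf and Tgfa probes were under background on every array. Of 19 MAPK feedback and immediate early genes 4 rose and 0 fell (4 and 0 adjusted over the list alone; list adjusted p 0.00470, and adjusted p = 0.107 with an estimated correlation): Ccnd1, Junb (0.56) and, at least 1.46-fold and 1.32-fold higher, Atf3 and Ier3. Of 29 cell cycle genes 4 rose and 1 fell (4 and 1 adjusted over the list alone; list adjusted p 0.129). The call on Egfr ended with median scaling (adjusted p 0.152) and with an intensity trend in the prior (0.0821), and of 3 other Egfr probes 2, above background on all 8 arrays, passed (-1.18 and -1.23, adjusted p 0.000517 and 0.00158) and 1, above it on 2 arrays, missed. That on Junb ended without CCl4 replicate 2 (adjusted p 0.0672) or vehicle replicate 1 (0.0697).

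With median scaling in place of quantile normalization 481 genes changed with CCl4 against vehicle, and the count was 917 without vehicle replicate 1. Median scaling also ended the calls on Cygb, Ccn2, Ephx1, Lrg1, Abcg8, Mvd, Psmd13 and Cox6c (adjusted p 0.0514 for Lrg1 to 0.283 for Psmd13), and the filter on probes above the receptor background on all 8 arrays ended those on the MAPK (0.0841) and NRF2 (0.0758) lists. Of 40 lists 28 shifted, 16 up and 12 down, and 0 passed with an estimated correlation, whereas 31 passed by fry, which tests a list's genes against no change.

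**Figure D1:**
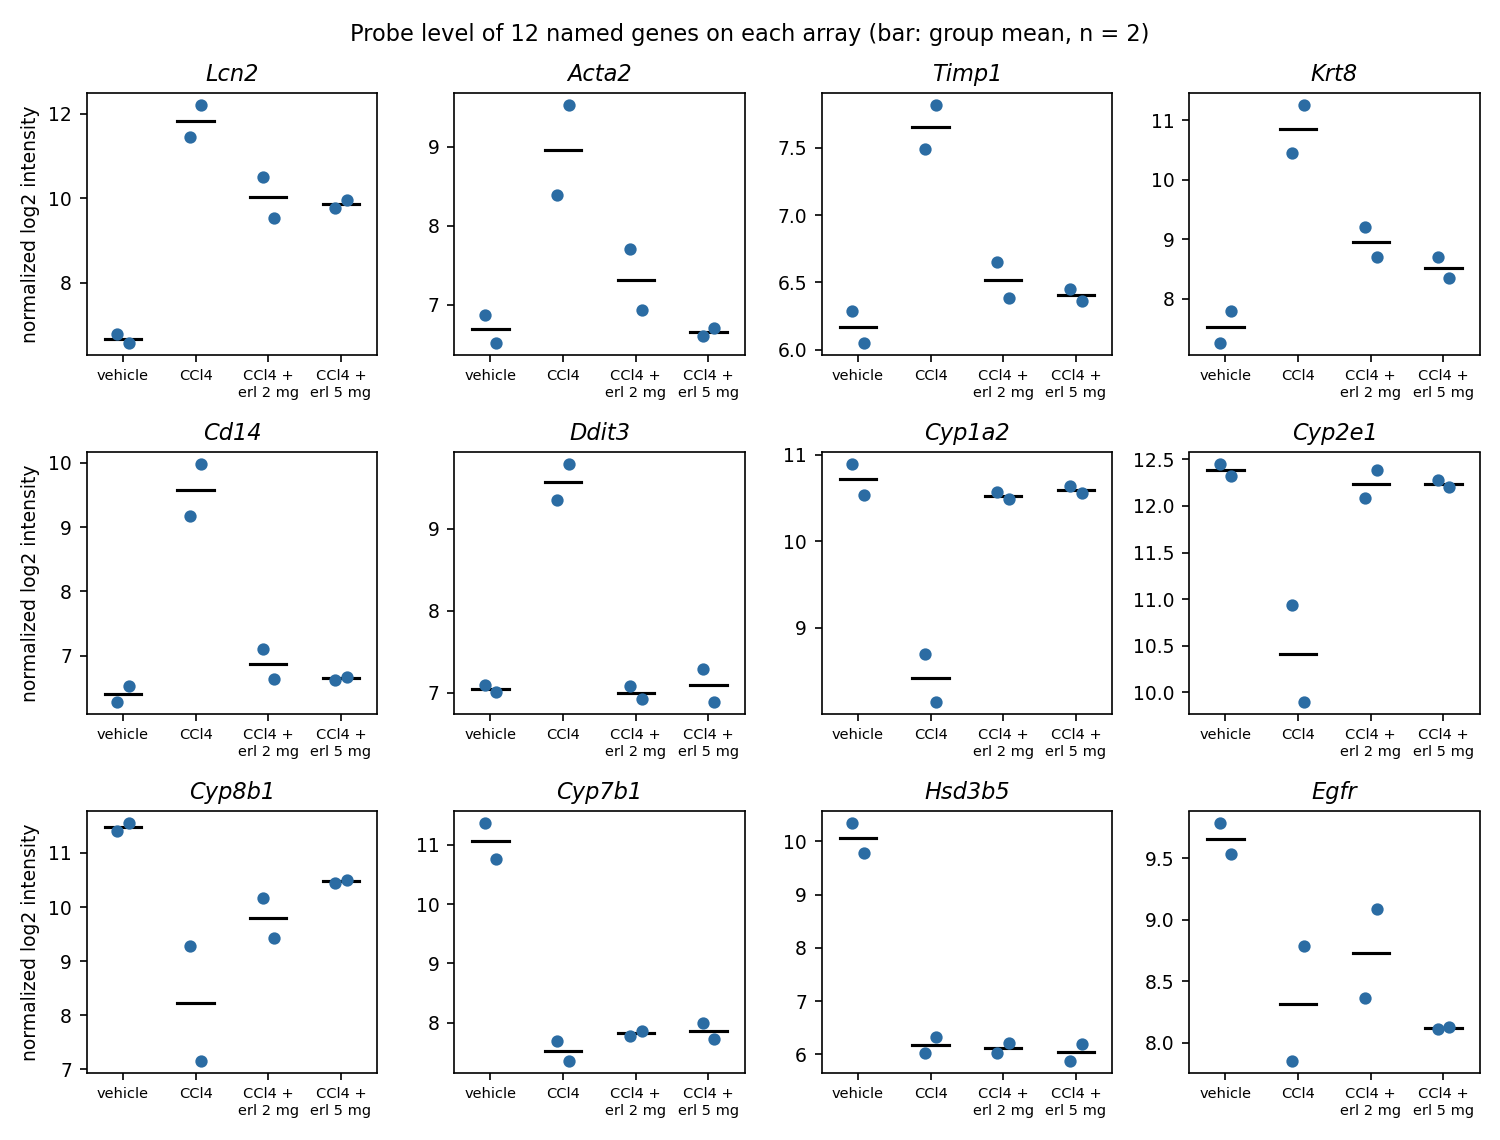
Normalized log2 intensity of 12 genes on each of the 8 arrays, with 1 panel per gene, 1 point per array and a bar at the group mean (n = 2). With CCl4, Lcn2, Acta2, Timp1, Krt8, Cd14 and Ddit3 were higher than with vehicle and Cyp1a2, Cyp2e1, Cyp8b1, Cyp7b1, Hsd3b5 and Egfr lower. With both erlotinib doses against CCl4, all but Cyp7b1, Hsd3b5 and Egfr differed in the opposite direction past the threshold.

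The comparison of both erlotinib doses with CCl4 alone asked how the CCl4-treated liver differed when erlotinib was given as well. Several genes that CCl4 had raised fell and several hepatocyte enzymes rose. Whether the receptor kinase was inhibited was not measured. No group received erlotinib without CCl4, so an effect of the drug alone cannot be told apart from a smaller effect of CCl4. The groups are separate arrays, so rises and falls are differences between groups and not changes over time. Cd14 fell by 2.81 ± 0.18 (adjusted p 6.30e-08), Ddit3 by 2.52 ± 0.13 (adjusted p 1.69e-08), Acta2 by 1.97 ± 0.24 (adjusted p 2.67e-05) and Timp1 by 1.19 ± 0.12 (adjusted p 5.58e-06). Cyp1a2 rose by 2.14 ± 0.14 (adjusted p 9.82e-08), Cyp2e1 by 1.82 ± 0.19 (adjusted p 8.24e-06), Car3 by 2.92 ± 0.30 and Hamp2 by 3.31 ± 0.22 (adjusted p 1.13e-07). Dbp was at least 6.67-fold higher (adjusted p 0.000238), but it varies with the time of day, and the time of death is not given.

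With both doses together, 4 arrays against 2, 1252 genes changed, 590 higher and 662 lower, 161 of them at least 2-fold. In 1227 of these all arrays of one side lay beyond those of the other, as in 27.2% of all genes tested, against 13.3% by chance. Further falls were those of Wfdc3 (-3.16 ± 0.18, a size left uncertain by the 2 of 4 erlotinib arrays under background), Serpina7 (-3.10 ± 0.22), Fkbp11 (-2.59 ± 0.12), Anxa2 (-2.52 ± 0.22), Krt18 (-2.31 ± 0.20), the TWEAK receptor Tnfrsf12a (-2.13 ± 0.12), Krt8 (-2.11 ± 0.20) and S100a11 (-2.05 ± 0.17). Further rises were those of the methyltransferase Inmt (2.56 ± 0.24), Rgs16 (2.35 ± 0.22), the uridine phosphorylase Upp2 (2.18 ± 0.23), Thrsp (2.12 ± 0.24), the folate enzyme Aldh1l1 (1.99 ± 0.13) and Cyp8b1 (1.91 ± 0.36). The count was 315 with median scaling and 647 without CCl4 replicate 2.

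Some genes of several hepatocyte functions rose with erlotinib. Of 28 urea cycle and amino acid breakdown genes 16 rose and 1 fell (18 and 1 adjusted over the list alone; median 0.50, list adjusted p 1.87e-14, and adjusted p = 0.0625 with an estimated correlation), Prodh being at 1.65 and Haao at 1.41. Of 49 cytochrome P450 and phase II genes 21 rose and 2 fell (26 and 2 adjusted over the list alone; list adjusted p 5.03e-13, and adjusted p = 0.0585 with an estimated correlation). The glutathione transferases Gsta1 (-1.14) and Gstp1 (-0.89) were those that fell. Of 32 complement and coagulation genes 13 rose and 0 fell (18 and 0 adjusted over the list alone; list adjusted p 6.02e-12, and adjusted p = 0.0804 with an estimated correlation), with Klkb1 at 1.28. Of 25 pericentral genes 13 rose and 2 fell (16 and 3 adjusted over the list alone; list adjusted p 7.40e-08, and adjusted p = 0.105 with an estimated correlation), and of 23 periportal genes 9 rose and 0 fell (13 and 0 adjusted over the list alone; list adjusted p 9.61e-07, and adjusted p = 0.0585 with an estimated correlation), Asl being at 1.31.

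Some lipid, bile acid and respiratory chain genes rose too. Of 29 fatty acid oxidation genes 13 rose and 0 fell (15 and 1 adjusted over the list alone). The list adjusted p was 3.25e-09 by camera, and adjusted p = 0.0804 with an estimated correlation. The thiolase Acaa1b was at 1.42 and the thioesterase Acot1 at 1.26 (0.68 on a second probe). Of 52 oxidative phosphorylation genes 13 rose and 0 fell (21 and 0 adjusted over the list alone; median 0.24, list adjusted p 3.25e-09, and adjusted p = 0.0585 with an estimated correlation). Of 24 bile acid genes 9 rose and 0 fell (10 and 0 adjusted over the list alone; list adjusted p 1.46e-07, and adjusted p = 0.118 with an estimated correlation): Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 1.78 ± 0.40 and the bile acid receptor Nr1h4 at 1.01. Of 22 fatty acid and triglyceride synthesis genes 8 rose and 1 fell (10 and 1 adjusted over the list alone; list adjusted p 1.31e-05, and adjusted p = 0.0585 with an estimated correlation), with Thrsp highest and Plin2 at -0.68. Of 17 cholesterol synthesis genes 3 rose and 0 fell (3 and 0 adjusted over the list alone; list adjusted p 0.0155, and adjusted p = 0.412 with an estimated correlation). The call on Cyp7a1 ended with the authors' processed values (adjusted p 0.0937), with median scaling (0.145) and without CCl4 replicate 2 (0.279), and that on cholesterol synthesis without CCl4 replicate 1 (0.172) or erlotinib 5 mg replicate 2 (0.106).

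Of 16 circadian clock genes 2 rose and 1 fell (4 and 1 adjusted over the list alone; list adjusted p 0.0129, and adjusted p = 0.417 with an estimated correlation): Dbp and Nr1d1 (1.5 ± 0.11, and 0.66 on its second probe) rose, and Nfil3, whose protein represses the targets of Dbp, changed by -0.76. Of 23 male-biased and growth hormone dependent genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; list adjusted p 0.000311, and adjusted p = 0.134 with an estimated correlation). The members that rose furthest were Cyp2b13 (1.60), the growth hormone receptor Ghr (0.79) and Acot3 (0.77). Of the 6 that rose 3, Cyp2b13, Acot3 and Cyp2b9 (0.61), are genes higher in females, so the shift of the list does not show a return of male-type expression. Serpina1e fell further, by 1.08. The call on circadian clock genes ended without CCl4 replicate 1 (adjusted p 0.0721), erlotinib 2 mg replicate 2 (0.0654) or erlotinib 5 mg replicate 1 (0.0530).

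Ribosomal protein genes fell, as did some chaperone and stress response genes. Of 44 cytosolic ribosomal protein genes 32 fell and 0 rose (36 and 1 adjusted over the list alone; median -0.59, list adjusted p 2.05e-24, and adjusted p = 0.0585 with an estimated correlation), Rpl12 being at -0.98. Of 26 unfolded protein and integrated stress response genes 10 fell and 0 rose (11 and 0 adjusted over the list alone; list adjusted p 7.81e-08, and adjusted p = 0.0590 with an estimated correlation), with Ddit3 leading, Creld2 at -1.56 and the chaperone Hsp90b1 at -0.95. Of 14 heat shock genes 5 fell and 0 rose (6 and 0 adjusted over the list alone; list adjusted p 0.000217, and adjusted p = 0.241 with an estimated correlation), with the co-chaperone Bag3 at -0.83 (a call that ended without CCl4 replicate 2, adjusted p 0.147). Of 24 proteasome genes 4 fell and 0 rose (6 and 0 adjusted over the list alone; list adjusted p 0.000167, and adjusted p = 0.134 with an estimated correlation).

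Of 33 interferon response genes 12 fell and 0 rose (13 and 1 adjusted over the list alone; list adjusted p 3.53e-06, and adjusted p = 0.241 with an estimated correlation), with Igtp at -1.30 and Isg15 at -1.07. Of 22 Kupffer cell and macrophage markers 6 fell and 0 rose (9 and 0 adjusted over the list alone; list adjusted p 6.62e-05, and adjusted p = 0.155 with an estimated correlation): beside Cd14, Cd9 was at -0.97 and the lectin Lgals3 was at least 2.18-fold lower. Of the other markers that led the rise with CCl4, Lyz1 (-0.40) and Gpnmb (-0.43) fell less and Lyz2 missed (-0.10, adjusted p 0.852). Against vehicle, Lyz1, Lyz2 and Gpnmb were higher with erlotinib (1.51, 1.70 and 1.84), and Cd14 had a value of 0.36 (adjusted p 0.400). The Gpnmb probe was under background with vehicle, which leaves the size of its difference uncertain. The endothelial list, which shares Mrc1 with the macrophage list, did not pass (0 rose and 1 fell, 0 and 1 adjusted over the list alone, list adjusted p 0.579).

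Of the matrix lists, basement membrane and matrix glycoprotein genes shifted, with 5 of 15 lower and 1 higher (5 and 1 adjusted over the list alone; list adjusted p 0.0198, and adjusted p = 0.147 with an estimated correlation). The laminin-binding nidogen Nid1 (-0.93) and Col4a1 (-0.56) fell and Col18a1 rose (0.60). The fibrillar collagen list did not pass, with 0 of 7 past the threshold (0 rose and 1 fell adjusted over the list alone, list adjusted p 0.767). Col1a1 had a value of -0.36 (adjusted p 0.0522) and Col3a1, on its dim probe, of 0.24 (adjusted p 0.160). Stellate cell markers also missed (0 rose and 2 fell of 22, 0 and 2 adjusted over the list alone; list adjusted p 0.168), although Acta2 and Vim (-0.44) fell, and so did the TGF-beta list (0 rose and 2 fell of 16, 0 and 2 adjusted over the list alone; list adjusted p 0.149) and matrix crosslinking and turnover (0 rose and 2 fell of 16, 0 and 3 adjusted over the list alone; list adjusted p 0.223). Egfr itself had a value of 0.10 ± 0.21 (adjusted p 0.881) and Hbegf, on its dim probe, of 0.24 (adjusted p 0.213). The list of MAPK feedback and immediate early genes, which lie downstream of the receptor, did not pass with both doses (0 rose and 3 fell of 19, 1 and 4 adjusted over the list alone; list adjusted p 0.208) or at 5 mg (2 rose and 3 fell, 4 and 3 adjusted over the list alone; list adjusted p 0.593). At 2 mg it was lower (0 rose and 2 fell, 0 and 4 adjusted over the list alone; median -0.12, list adjusted p 0.0337, and adjusted p = 0.249 with an estimated correlation), which ended without CCl4 replicate 2 (0.124) or erlotinib 2 mg replicate 1 (0.101), and between the doses the list missed (adjusted p 0.0817). The filters against the receptor background ended the call on basement membrane and matrix glycoproteins (adjusted p 0.0637 and 0.226).

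Of 40 lists 19 shifted, 12 up and 7 down, 18 passed by fry and 0 passed with an estimated correlation. Several lists that CCl4 had raised did not pass with erlotinib. They were antigen presentation (median -0.03), cholangiocyte (0.003), oncofetal (0.0001), neutrophil (-0.09), NRF2 target (0.04) and metallothionein and acute phase genes (-0.11), besides those given above. Median scaling ended the calls on Dbp, Thrsp, Col4a1, Nr1h4, Cyp2b13, Ghr, Acot3 and Bag3 (adjusted p 0.0515 for Thrsp to 0.243 for Ghr), an intensity trend in the prior those on Acta2 (0.0582) and Cyp8b1 (0.229), and the filter on all 8 arrays that on Kupffer cell and macrophage markers (0.0781).

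**Figure D2:**
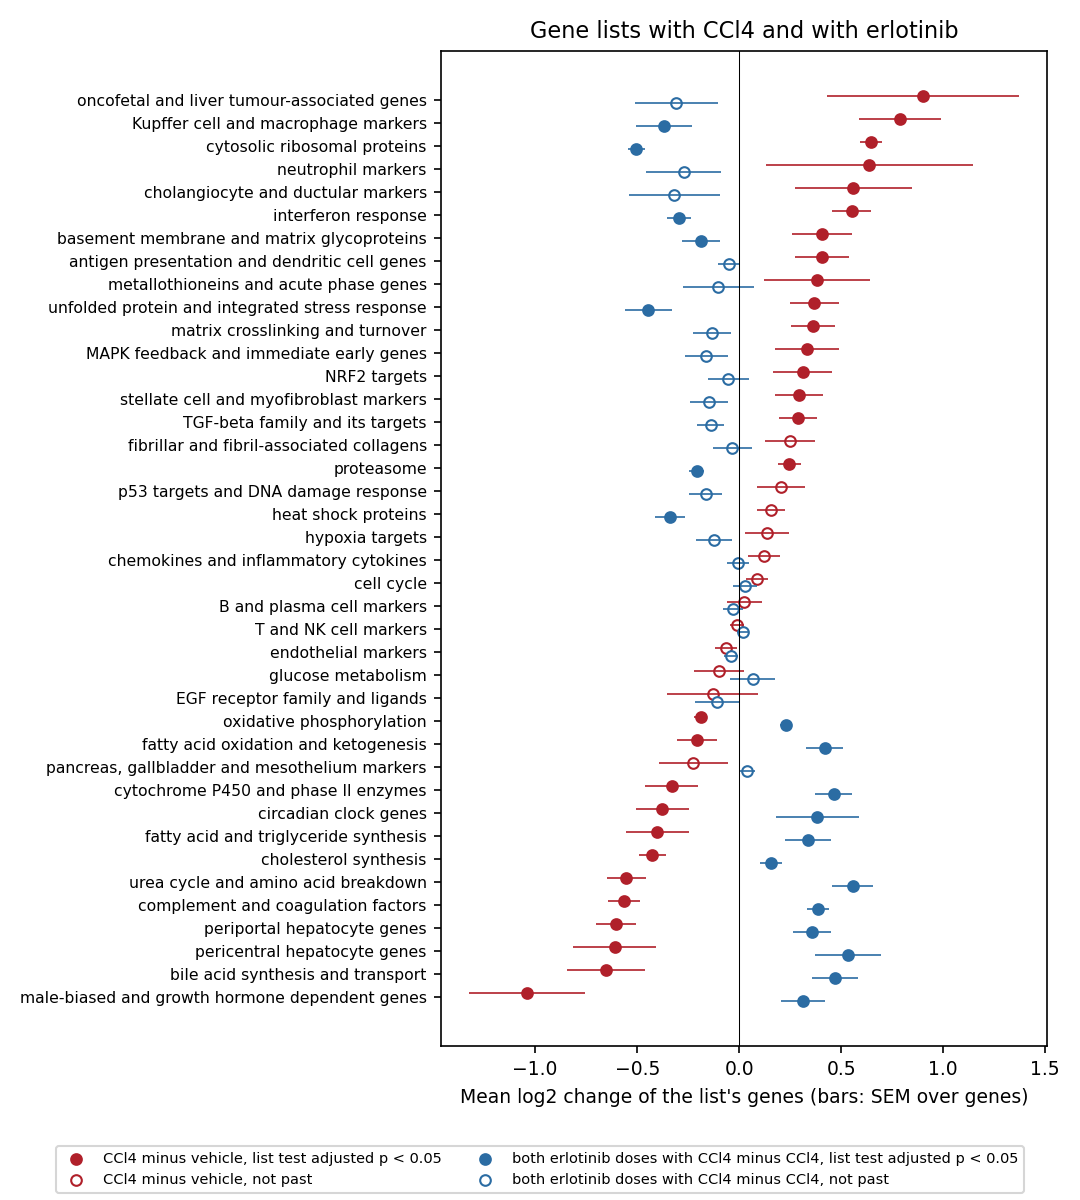
Mean log2 change of the genes of 40 lists for CCl4 minus vehicle (red) and both erlotinib doses with CCl4 minus CCl4 (blue), with bars of the SEM over genes, filled where the list passed the camera test at an adjusted p under 0.05. Ribosomal protein genes stood at a median of 0.75 with CCl4 and -0.59 with erlotinib, and urea cycle and amino acid breakdown genes at -0.49 and 0.50, and with an estimated correlation 0 of these lists passed.

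Genes that moved with CCl4 mostly moved the opposite way with erlotinib. Of the 1398 genes changed by CCl4, 909 (65.0%) changed the other way with both doses of erlotinib against CCl4. Of these, 484 were higher with CCl4 and lower with erlotinib, and 425 were lower with CCl4 and higher with erlotinib. Across all genes the changes correlated at r = -0.810 (genes are not independent replicates, and no p is given). The 2 comparisons share the CCl4 arrays, and simulated unchanged groups sharing them gave r = -0.578. The covariance was -0.0915, beside -0.00860 in the simulation and -0.0802 when the 2 CCl4 arrays were split between the comparisons, which left r at -0.627 and -0.678. Unchanged groups split in that way gave r of at most 0.0257 in size. The simulation draws each array independently, so it does not cover a batch or animal shared by the 2 CCl4 arrays, which would also make r negative. The lists themselves were called with both CCl4 arrays in each comparison, so part of the excess in opposite changes may come from the shared arrays.

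Only 5 genes changed the same way in both comparisons, a number that the shared CCl4 arrays lower by construction, as they raise the number of opposite changes. Fndc10 (0.76 and 0.60), the glutathione transferase Gstm2 (0.76 and 0.41) and the histone gene H4c8 (0.56 and 0.49) rose in both, and Serpina1e (-3.35 and -1.08) and the prostaglandin transporter Slco2a1 (-0.58 and -0.50) fell in both. These 5 were named after their values were seen. Another 484 genes changed with CCl4 and missed the threshold with erlotinib, which does not show that they stayed as they were.

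**Figure D3:**
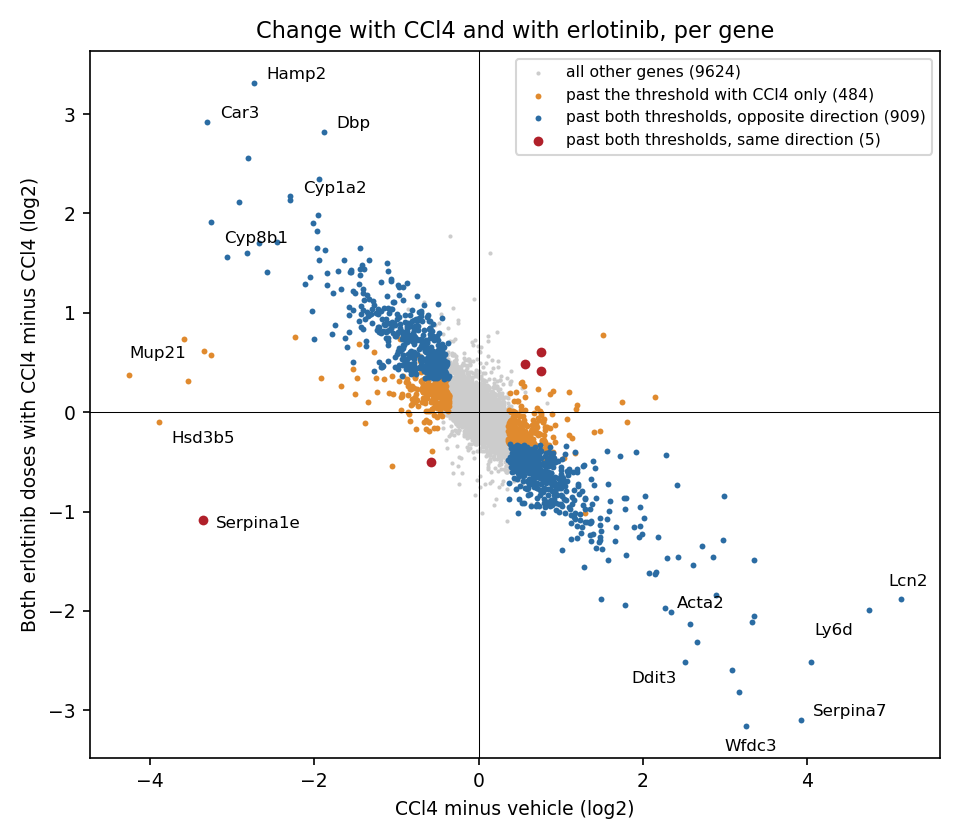
Log2 change per gene with CCl4 against vehicle (horizontal) and with both erlotinib doses against CCl4 (vertical), as fitted, for 11022 genes. Of the genes changed by CCl4, 909 (blue) changed the opposite way with erlotinib, 5 (red) the same way and 484 (orange) missed the threshold with erlotinib, and the grey points include 338 genes that passed with erlotinib alone.

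Taken separately, each dose gave a like picture against CCl4. At 2 mg 952 genes changed, 461 higher and 491 lower, and at 5 mg 999 changed, 486 higher and 513 lower; with median scaling the split at 2 mg was 59 higher and 98 lower. Cyp1a2 rose by 2.10 ± 0.16 at 2 mg and 2.17 ± 0.16 at 5 mg, Cyp2e1 by 1.82 ± 0.22 at each dose and Car3 by 2.88 ± 0.35 and 2.95 ± 0.35. Ddit3 fell by 2.56 ± 0.16 and 2.48 ± 0.16, Cd14 by 2.70 ± 0.20 and 2.92 ± 0.20, Timp1 by 1.14 ± 0.14 and 1.25 ± 0.14 and Acta2 by 1.64 ± 0.27 and 2.30 ± 0.27, with adjusted p 0.000810 and 3.82e-05 for Acta2. Col1a1 had values of -0.31 (adjusted p 0.213) and -0.42 (adjusted p 0.0617). Without CCl4 replicate 2 the counts were 521 and 525, and without erlotinib 5 mg replicate 2 the count at 5 mg was 602.

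At both doses 756 genes changed in the same direction, a number that the shared CCl4 arrays raise, and 0 changed in opposite directions. The changes at the 2 doses correlated at r = 0.889 across genes. Unchanged groups simulated against the same CCl4 arrays gave 0.499, and with the CCl4 arrays split r was 0.691 and 0.696. A batch shared by the 2 CCl4 arrays is not covered by this simulation either. The covariance was 0.0811 beside 0.00859 in the simulation. Of 40 lists 21 shifted at 2 mg, 12 up and 9 down, and 20 at 5 mg, 11 up and 9 down, and with an estimated correlation 0 did at either dose.

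The direct comparison of 5 mg with 2 mg asked whether the doses differed. Acot1, an acyl-CoA thioesterase (0.96 ± 0.15, adjusted p 0.0439), and Cyp4a31, a fatty acid hydroxylase (0.85 ± 0.13, adjusted p 0.0439), were higher at 5 mg, both of families regulated by the lipid sensor PPAR-alpha. These were the only 2 of 11022 genes past the threshold by limma, 505 had an unadjusted p under 0.05, and the median half-width of the 95% interval was 0.27 on the log2 scale. Among genes that missed it, the values of the immediate early genes Dusp1 and Zfp36 were 0.93 and 0.71 (adjusted p 0.0655 each), and that of Ccnd1 was -0.88. A second Acot1 probe, above background on all 8 arrays, gave 0.68 with both doses against CCl4, where the first gave 1.26. With CCl4 against vehicle it missed (-0.09, limma adjusted p 0.810), where the first gave -0.97. Its difference between the doses is not given here. The calls on Acot1 and Cyp4a31 ended with the authors' processed values, without background correction and with median scaling, where 0 genes passed. The count was 7 without erlotinib 2 mg replicate 2 and 0 without erlotinib 2 mg replicate 1 (adjusted p 0.348 for Acot1 and 0.216 for Cyp4a31) or either vehicle array (0.128 for each gene). Acot1 also missed without erlotinib 5 mg replicate 1 (0.203) or 2 (0.111), and Cyp4a31 without erlotinib 2 mg replicate 2 (0.147) or erlotinib 5 mg replicate 1 (0.227).

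Complement and coagulation genes (median 0.16, list adjusted p 0.00105) and fatty acid oxidation genes (0.08, 0.00622) were higher as lists at 5 mg than at 2 mg, and oncofetal genes lower (-0.16, 0.00861), but the adjusted p-values of the 7 lists that shifted were 0.508 to 0.647 with an estimated correlation, and 0 lists passed by fry. Single members past the threshold were 0 of 32 (0 adjusted over the list alone), 1 of 29 (2 adjusted over the list alone) and 0 of 14 (0 adjusted over the list alone). Without erlotinib 2 mg replicate 1 the adjusted p was 0.116 for complement and coagulation factors, 0.225 for fatty acid oxidation and ketogenesis and 0.985 for oncofetal and liver tumour-associated genes, which also missed without erlotinib 5 mg replicate 1 (0.0814).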

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

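The tests of explanations for the ribosomal protein, macrophage and clock patterns were chosen after the results were seen, apart from that of the clock genes opposite in phase to Dbp. The dose groups differed in 2 genes and 7 lists when tested directly. Acot1 (0.96) and Cyp4a31 (0.85) were higher at 5 mg than at 2 mg. Of the lists, complement and coagulation factors (median 0.16), metallothioneins and acute phase genes (0.11), fatty acid oxidation (0.078) and p53 targets (0.044) were higher, and oncofetal genes (-0.16), cholangiocyte markers (-0.16) and basement membrane glycoproteins (-0.12) lower. With an estimated correlation the adjusted p of these lists was 0.508 to 0.647, and 0 passed by fry. Without erlotinib 2 mg replicate 1 the calls on complement (adjusted p 0.116), fatty acid oxidation (0.225), oncofetal (0.985), cholangiocyte (0.794) and basement membrane genes (0.116) ended, and 0 genes passed. Without erlotinib 2 mg replicate 2 those on acute phase (0.0638), basement membrane (0.0638) and p53 genes (0.207) ended. Without erlotinib 5 mg replicate 1 oncofetal (0.0814) and p53 genes (0.189) missed, and without replicate 2 acute phase (0.666), cholangiocyte (0.576) and basement membrane genes (0.173). Other lists passed against CCl4 at 1 dose alone, and for those not named here the direct comparison of the doses did not pass.

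Probes without a current gene symbol, which no comparison of the report uses, also responded. Of 980 tested, 113 changed with CCl4 (58 higher and 55 lower) and 98 with both doses of erlotinib (46 higher and 52 lower). With CCl4, for example, probe ILMN_1213817 fell by 2.33 ± 0.25. Between the doses 0 passed by limma, with 45 at an unadjusted p under 0.05.

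Ribosomal protein genes were higher with CCl4 (median 0.75, SD over 44 genes 0.353) and lower with erlotinib, with adjusted p = 0.0711 and adjusted p = 0.0585 with an estimated correlation. RNA quality or a bias toward short transcripts may move ribosomal protein genes. Oxidative phosphorylation genes, of which many are short too, had a median of -0.18 (SD 0.243) with CCl4. This cannot exclude such a bias, since neither transcript length nor RNA quality was measured. These genes also moved with the hepatocyte lists, down with CCl4 and up with erlotinib (median 0.24), which could hide a bias. The background correction and scaling do not account for the ribosomal protein pattern, since the lowest median over 3 other scalings was 0.50, with median scaling. A batch that coincides with the groups was not tested and stays open, as do RNA quality, a length bias and an effect of CCl4 on ribosomal protein transcripts.

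Some macrophage markers were higher with CCl4, and hepatocyte gene lists were lower by camera with the preset correlation. With an estimated correlation 0 lists passed. A lower share of hepatocytes may raise the markers of all other cells alike, but the 27 measured endothelial markers outside the macrophage list had a median of -0.0245 (mean -0.05, SD 0.277) and the 21 macrophage markers one of 0.40 (mean 0.85, SD 0.921), with a permutation p of 1e-05, the smallest that 100000 resamples can give, which treats genes as independent. Among markers above background on both vehicle arrays the medians were -0.09 (15 endothelial) and 1.17 (9 macrophage), p 0.000800, and the 22 stellate markers, with a median of 0.12 (mean 0.29), moved as a lower share would move them. Without 1 CCl4 array the macrophage list kept a median of at least 0.32 (higher adjusted p 2.24e-09), against a single array as the cause, but with all arrays it missed with adjusted p = 0.0722 with an estimated correlation. A lower share is thus argued against only as the whole cause, and more macrophages, higher expression in each or a loss of endothelial cells was not tested and stays open.

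With CCl4 the clock list missed its threshold with an estimated correlation. Of 6 clock output genes Hlf, Per1 and Per2 missed as well (adjusted p 0.0559 to 0.0738). Dbp, Nr1d1 and Tef were lower, and the median of the 6 was -0.49. Death at another time of day may cause this and would move Arntl, Npas2, Clock and Nfil3 the other way; their median was 0.0155 (mean SE 0.150), with Arntl and Npas2 under background on every array, so time of death and an effect of CCl4 cannot be told apart. No single CCl4 or vehicle array accounts for the lower median, which lay between -0.44 and -0.56 with 1 of these arrays left out. Leaving out an erlotinib array cannot move this median, so those fits test nothing and make the SD over all 8 fits (0.0438) smaller.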

How the results depend on the processing

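Of the alternatives, the 2 filters on the receptor background were chosen after seeing the data. Of list tests, 0 passed with an estimated correlation in any of the 5 comparisons, where 28 (CCl4), 21 (2 mg), 20 (5 mg), 19 (both doses) and 7 (5 mg against 2 mg) passed with the preset one. With median scaling the genes changed were 481 for CCl4, 157 at 2 mg, 169 at 5 mg, 315 for both doses and 0 between doses; the cause was not tested. The other alternatives left the first 4 counts within 1.5 times (CCl4 1185 to 1410), apart from arrays left out.

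Leaving out 1 array, the counts ranged from 917 (without vehicle replicate 1) to 1377 for CCl4, 521 to 932 at 2 mg, 525 to 985 at 5 mg and 647 to 1168 for both doses, the lowest of these 3 without CCl4 replicate 2; lists ranged over 28 to 30, 19 to 21, 20 to 22 and 18 to 22. Fewer arrays give a wider error.

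Between the doses, genes changed (2) became 0 with the authors' values, no background correction, the mean of probes, only the compared arrays or either receptor filter, 5 with no filter, 4 with a trend and robust prior, and 0 to 7 with 1 array left out. Lists shifted (7) became 0 by fry, 4 with median scaling, 2 with no filter, 2 with the filter on all 8 arrays and 4 to 10 with 1 array left out. Circadian clock genes, not past between doses (median -0.04, mean 0.02), passed in the other direction without CCl4_erlotinib_2mg replicate 1 (median -0.15, adjusted p 0.0387) and upward without CCl4_erlotinib_2mg replicate 2 (0.25, adjusted p 0.000684); the cause was not tested.

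The correlation of CCl4 and erlotinib changes (-0.810) was -0.840 with the filter on all 8 arrays, -0.627 and -0.678 with the CCl4 arrays split and -0.846 to -0.779 with 1 array left out. Of the values for named genes, 6762 kept their side of the threshold, 552 were weaker, 14 stronger and 0 reversed; for lists these were 3058, 200, 61 and 1. Values that missed the threshold both times changed sign 109 times. Of 371 called named values 185 kept their call under all settings that leave out no array and 292 whichever array was left out. Signal over background limits 4405 genes that were under it on every array.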

Other observations

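The tests of male-biased genes in this part, and the comparison of erlotinib with vehicle, were chosen after seeing the data. Glucose enzymes moved both ways with CCl4 (4 of 21 rose and 4 fell, list adjusted p 0.341 by camera): the glycolytic Pkm (1.11) and Ldha (0.95) rose, and glycogen phosphorylase Pygl (-1.06) and glucose-6-phosphatase G6pc (-1.05) fell. Of p53 targets (list adjusted p 0.0588) the cell cycle inhibitor Cdkn1a rose by 2.01, and with erlotinib it changed by -1.06 (list adjusted p 0.0725). Among chemokine and cytokine genes (list adjusted p 0.129) Vcam1 (0.93) and Cxcl16 (0.78) rose and Cxcl12 changed by -0.86. Replication licensing gene Mcm4 rose with CCl4 (0.66) and changed by -0.70 with erlotinib. Hypoxia targets had list adjusted p-values of 0.168 in both, and pancreas, gallbladder and mesothelium markers, which would mark stray tissue, of 0.116 and 0.613, with Cela1 at -1.91 with CCl4.

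Against vehicle, both doses of erlotinib with CCl4 left 389 genes changed (215 higher and 174 lower), and 281 of these had changed the same way with CCl4 alone. Lcn2 (3.26 ± 0.22), Orm2 (2.30), Cyp4a14 (2.29), Cd63 (1.86) and Lyz2 (1.70) were higher, and Mup21 (-3.88), Cyp7b1 (-3.22), Mup2 (-2.85) and G6pc (-1.59) lower. Of the genes changed by CCl4, 1347 (96.4%) had an erlotinib mean on the vehicle side of the CCl4 mean, a share that the shared CCl4 arrays raise. With the CCl4 arrays split, the median share of the CCl4 change that was absent with erlotinib was 71.5% and 53.5%. It was taken over those changed genes that differed at least 2-fold from vehicle on the CCl4 array used as reference. Of genes changed with erlotinib, 338 had missed the threshold with CCl4, such as the rate-limiting haem synthesis gene Alas1 (-1.01) and Klf9 (1.04), which does not show that CCl4 left them as they were.

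Several male-biased genes lowered by CCl4 stayed low with erlotinib, and a candidate explanation is that male-type growth hormone signalling returned less than other hepatocyte functions. In the 6 such genes lowered at least 2-fold (Cyp2d9, Cyp7b1, Elovl3, Hsd3b5, Mup2 and Serpina1e) a median of 96.8% of the CCl4 change remained, against 25.5% in 143 other genes (exact rank-sum p 4.73e-06), with a range of 53.1%, in Cyp2d9, to 132%. Cyp2d9 no longer passed against vehicle (adjusted p 0.0935). Among the genes lowered by any amount, which add Mup5 and Selenbp2, the median was 90.5% in 8 against 27.5% in 643 others (p 0.000778), and Selenbp2 goes against the hypothesis: it fell by 0.63 with CCl4 and rose by 0.70 with erlotinib, with -11.4% remaining. These p-values treat genes as independent, which they are not. Hsd3b5, Elovl3 and Mup5 were under background on both CCl4 arrays, which leaves their shares uncertain, and without genes of that kind the medians of the first groups were 85.3% in 4 genes and 24.9% in 137 (p 0.000430). Mup6, Mup20 and Mup21 (81.5%, 82.2% and 91.2% remaining), male-biased but outside the list, stand in neither group. Nor do the male-biased list genes that missed the threshold with CCl4 (limma adjusted p 0.135 to 0.994). These were C6 (-0.30), Cyp4a12a (-0.74), Cyp4a12b (0.17), Moxd1 (-0.004) and Slco1a1 (-0.09), so a loss of male-type expression as a whole is not shown. With median scaling the medians of the first groups were 97.8% and 29.6%. Growth hormone was not measured, and the pattern was found and tested on the same arrays.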
